A study of Mus musculus with 8 samples.

How the data were processed

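The data are gene-level counts from RNA-seq of 8 samples of sorted mouse spleen cDCs, 4 WT and 4 CKO, all cultured with 100 nM CpG-B for 9 h. Per the labels' protocols, RNA was extracted with a micro kit, polyA RNA was copied into cDNA with a SMART-Seq low-input kit, and libraries were made with a Vazyme kit. Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.2.1 and the mm10 build were used. The counting program, its annotation and its strand setting are not given in the sources used here. The deposited table holds whole-number counts per gene without normalization, and per the file headers it also gives each gene's position, strand and length. Neither kit is stated to mark strand, so reads of overlapping genes on opposite strands may not be told apart, which concerns genes whose exons overlap. Among the genes named these are Rtn4 with Eml6, Heatr1 with Lgals8, Tesk1 with Cd72, Il1b with Il1bos, Oasl1 with Gm13822, Il27 with Apobr, Cxcl10 with Art3, Irf7 with Phrf1, Ly75 with Gm13571, Pcbp1 with 1600020E01Rik and Alas2 with Apex2. Low-input cDNA amplification can give each library its own dependence on GC content and length, which was measured.

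Groups were taken from the genotype labels. The labels give each library its own number, with none shared between the groups, so no paired fit was planned. They do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. No 2 libraries were copies: the smallest chi-square per degree of freedom between any pair was 46.2. No sequencing batch or date is given in the sources used here. No column of the table was left unused.

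Of 31053 genes in the table, 12911 had 0 counts in all libraries. Gene IDs were matched to GENCODE M21, which held 31011 of them, 29859 with identical chromosome, start, end and strand. That annotation supplied transcript GC content, biotype and exon overlaps. Fold changes are CKO over WT on the log2 scale. The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, robust dispersions, and the quasi-likelihood F test over the 11702 genes kept, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-normalised, and log2 CPM used a prior count of 2.

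Tests, alternatives, 43 gene lists, cell type markers and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest changes in each direction among changed genes with a mean of at least 5 CPM in the higher group and no overlap between WT and CKO libraries, leaving out predicted genes and immunoglobulin and T cell receptor segments. It also named the 5 smallest p-values in each direction, 10 fixed readouts, and up to 4 members of each list described, by p-value. There were 818 genes eligible for the first part. Genes named outside the rule, and which genes were followed through the alternatives, were chosen after the values were seen. The former are said to be so where they appear. The lists were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the 38 lists with at least 5 measured members), and again with an estimated correlation and with fry. Summed marker CPM was compared with exact two-sided permutation tests of 4 against 4 (70 arrangements, smallest p 0.0286), adjusted over 14 lists.

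Some analyses were chosen after seeing the data. A correction for GC content and length was added once a trend was seen: in each library, deviations of log2 CPM from the gene's mean were fitted with natural splines (5 degrees of freedom) of transcript GC content and log2 gene length over genes at 1 CPM or more, and the fitted trend entered edgeR as an offset. GC values were at hand for 99.9% of the genes tested. The mean log2 CPM of the B cell markers as a covariate, exact permutation tests of each list's mean log2 CPM, and 5 further lists were also added then: ribosome biogenesis, aminoacyl-tRNA synthetases, iron uptake and storage, nuclear import and export receptors, and 1 more, whose result is not reported here.

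Alternatives planned were RLE, upper quartile and total-count scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, dispersions without the robust option, 1 surrogate variable (sva 3.50.0), a cDC1 minus cDC2 marker covariate, thinning to the smallest library, protein-coding genes only, leaving out each library in turn, and other thresholds. A covariate of Y-linked genes was planned only if libraries differed by over 3 log2 units in their mean; they differed by 1.08, so it was not run.

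Library totals of 25304765 to 40950088 counts limit precision little for abundant genes; the spread between libraries and their number set it. The test was checked on counts simulated for the 11702 genes from the real means, dispersions and library sizes, with 200 genes changed. It recovered 16.4% of 1.5-fold, 59.7% of 2-fold and 92.4% of 4-fold changes for CKO against WT, and called 0.05% of unchanged genes. With GC and length trends like the observed ones added, it called 0.77% of unchanged genes without the correction and 0.10% with it. The added trends came from the same spline model that the correction fits, so their removal was built in. Counts were drawn independently for each gene, without the variation that genes share between real libraries. These rates therefore need not hold for the real data. Figures were drawn with matplotlib.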

Results

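Conventional dendritic cells (cDCs) of the mouse spleen, the antigen-presenting cells that prime T cells, were profiled by RNA-seq after activation through Toll-like receptor 9. Splenocytes enriched to about 20% dendritic cells were cultured with 100 nM CpG-B, a synthetic ligand of that receptor, for 9 h. Lineage-negative, MHC class II-positive, CD11c-positive cells were then sorted and sequenced. There were 4 wild-type (WT) libraries, named D142, D150, D154 and D164, and 4 libraries labelled CKO, named D146, D149, D163 and D169. The sources used here do not name the gene deleted in CKO, so its level was not checked. Every library came from stimulated cells, so the comparison was between genotypes after activation and not of activation itself. The series title puts the question as one of an immunosuppressive state of dendritic cells after Toll-like receptor stimulation.

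Counts assigned to genes ranged from 25304765 in CKO D169 to 40950088 in WT D150. Ccr7, which encodes the receptor that guides mature dendritic cells to lymph nodes, took the largest share of counts in 7 of the 8 libraries, at 1.84% to 2.31%, and Actb led in CKO D146. Pearson correlations of log2 CPM (counts scaled to a common library size) between libraries lay between 0.957 and 0.988. The first principal component held 36.0% of the variance and separated the genotypes. CKO D146 correlated with the WT libraries (median Pearson r 0.976) as much as with the other CKO libraries (0.975). The second, at 19.0%, set CKO D149 apart from the other 7. Xist had 0 counts in all 8 libraries and the Y-linked Ddx3y had at least 1565 in each, so the sexes of the libraries did not differ between genotypes.

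Tgfb1, which encodes the suppressive cytokine TGF-β1, fell from 50.2 ± 3.04 CPM in WT to 11.96 ± 9.91 CPM in CKO (mean ± SD, n = 4 each). Fscn1, which encodes the actin-bundling protein of mature dendritic cells, fell from 4446 ± 681 to 1375 ± 781 CPM, and Il1b fell from 569 ± 41.5 to 329 ± 55.9 CPM. The prostaglandin synthase gene Ptgs2 rose from 82.6 ± 23.7 to 189 ± 23.3 CPM, and the transferrin receptor gene Tfrc rose from 8.87 ± 2.53 to 26.4 ± 10.1 CPM. The costimulatory genes Cd80 and Cd86 and the receptor gene Ccr7 did not pass the test.

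Of 11702 genes tested, 1038 differed at an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 503 higher and 535 lower in CKO. The balance of directions depended on the scaling, since total-count scaling gave 1080 higher and 311 lower. With the B cell marker covariate the count was 407, 256 higher and 151 lower. Of the 1038 genes of the main fit, 327 differed at least 2-fold, 162 higher and 165 lower, and the smallest log2 difference called was 0.36. The calls lay close to the threshold: the count was 347 without WT D142, 82 without WT D150, 138 without WT D154, 70 without CKO D163 and 457 without CKO D169. Log2 fold changes also followed transcript GC content and gene length across genes, which are not independent replicates (Spearman -0.32 and 0.29), and 643 of the 1038 genes kept their call and sign after each library's own trend was removed.

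**Figure D1:**
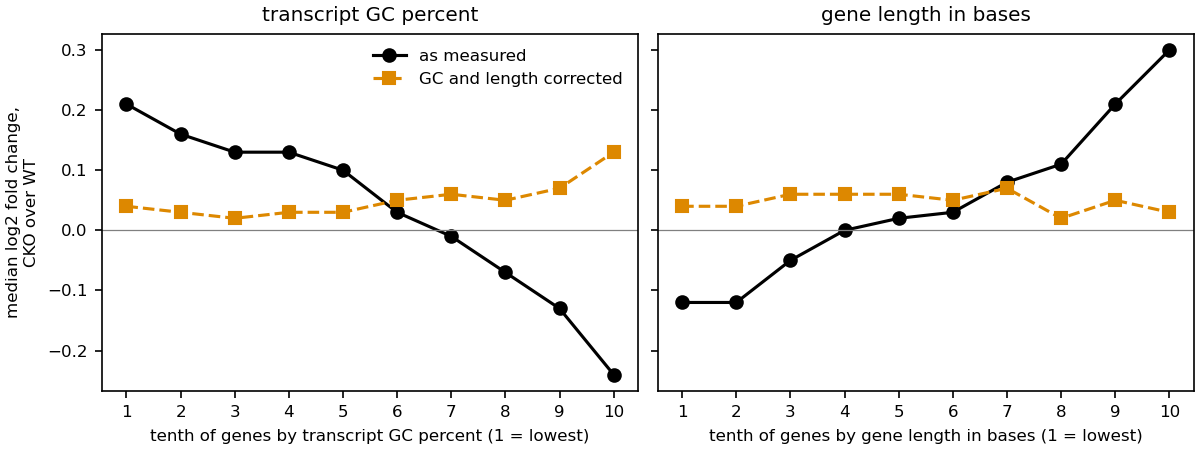
Median log2 fold change (CKO over WT, vertical axis) in 10 equal groups of the genes with a mean of at least 1 CPM, ordered by transcript GC percent (left) or gene length in bases (right). Circles are values as measured and squares are values after removal of each library's GC and length trend. From lowest to highest GC percent the measured median ran from 0.21 to -0.24, and from shortest to longest genes from -0.12 to 0.30.

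Among the 818 changed genes with a mean of at least 5 CPM in the higher group and no overlap between the genotypes, predicted genes and receptor segments left out, the largest decrease was in Epn1, which encodes the clathrin adaptor epsin 1 (chromosome 7, 5080235 to 5098178, mm10). Its log2 fold change was -2.73 ± 0.49 (SE), from 13.5 ± 1.24 to 1.99 ± 1.85 CPM; CKO D146, at a log2 CPM of 2.24, lay above the other CKO libraries, and without it Epn1 changed by -3.58. Its call was lost without WT D150 or CKO D163 (highest adjusted p = 0.0579). Tgfb1 (chromosome 7, 25687002 to 25705077) followed at -2.06 ± 0.41, with all 4 CKO libraries below all 4 WT libraries. Tgfb1 changed by -2.83 without CKO D146, its highest CKO library, and its call was lost without WT D150, WT D154 or CKO D163 and without the low-count filter (highest adjusted p = 0.0678). Klc2, a kinesin light chain, changed by -2.02 ± 0.33. Ass1, the argininosuccinate synthase that regenerates arginine from citrulline, changed by -1.99 ± 0.39, from 91.4 ± 33.2 to 23.1 ± 13.4 CPM. Others among the 10 largest decreases were Zfp628, the natriuretic peptide receptor gene Npr1, the kinase gene Tesk1, Wdtc1 and Fcgr1, with log2 fold changes from -1.89 to -1.77. In edgeR's test the adjusted p of the genes named here ran from 0.01001 for Zfp628 to 0.0259 for Tesk1. Exons of Tesk1 overlap those of Cd72, so its counts are less certain.

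The decreases with the smallest p-values were in more abundant genes. Rtn4, an endoplasmic reticulum-shaping reticulon (chromosome 11, 29692947 to 29744331), fell from 96.3 ± 7.17 to 34.2 ± 7.25 CPM (edgeR adjusted p = 0.00501), and its exons overlap Eml6. Ube2q1, a ubiquitin-conjugating enzyme, fell from 109 ± 4.96 to 34.9 ± 10.1 CPM with the same adjusted p in edgeR. Tmbim6, an endoplasmic reticulum membrane protein that restrains cell death, fell from 587 ± 110 to 211 ± 28.6 CPM, and WT D164 was the lowest of the WT libraries. Mbd2, a reader of methylated DNA, fell from 849 ± 100 to 340.0 ± 64.7 CPM. Ppp2cb, a catalytic subunit of protein phosphatase 2A, fell from 113 ± 14.3 to 40.9 ± 11.1 CPM. All 5 kept their call under every alternative fit at an adjusted p of 0.05.

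Among the same 818 genes the largest increase was in Utp20, a component of the small-subunit processome that matures ribosomal RNA (chromosome 10, 88746607 to 88826804). It rose from 1.67 ± 0.66 to 6.18 ± 2.13 CPM, a log2 fold change of 1.88 ± 0.35 (SE). Utp20 was followed by Fam199x at 1.86. Heatr1, another processome gene, changed by 1.601 ± 0.38, although its exons overlap Lgals8 and CKO D149 lay below the other CKO libraries. Tfrc (chromosome 16, 32608920 to 32632794) changed by 1.57 ± 0.30. The ETS-family transcription factor gene Ehf rose from 82.1 ± 54.0 to 235 ± 54.1 CPM, a log2 fold change of 1.51 ± 0.41. The rest of the 10 largest increases were the actin-binding gene Ablim1, the DNA replication and repair gene Rif1, Ercc6l2, the mannosidase gene Manea and the nuclear import receptor gene Ipo7, with log2 fold changes from 1.43 to 1.55. In edgeR's test the adjusted p of these 10 genes ran from 0.0114 for Rif1 to 0.0437 for Ehf. Only Rif1 and Ercc6l2 of the 10 kept their call in every alternative fit. Ehf lost it in 9 of 23 fits (highest adjusted p = 0.179) and Heatr1 in 6 of 23 (0.158). Fam199x lost it in 5 of 22 (0.0985) and Utp20 in 4 of 22 (0.0721).

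The increases with the smallest p-values included Rasgrp3, an activator of Ras, which rose from 9.98 ± 1.44 to 23.9 ± 3.62 CPM (edgeR adjusted p = 0.00928). Eprs, a tRNA synthetase gene, rose from 61.2 ± 6.29 to 131 ± 27.8 CPM, and the processome gene Mphosph10 rose from 13.8 ± 1.59 to 29.5 ± 5.06 CPM. Zmynd19 changed by 1.36 ± 0.19 (SE) on the log2 scale and Zfp638 by 1.11 ± 0.16. All genes named by size of change or by p-value, in both directions, were still past the threshold after the GC and length correction. Not all of them kept their call in every other alternative fit.

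**Figure D2:**
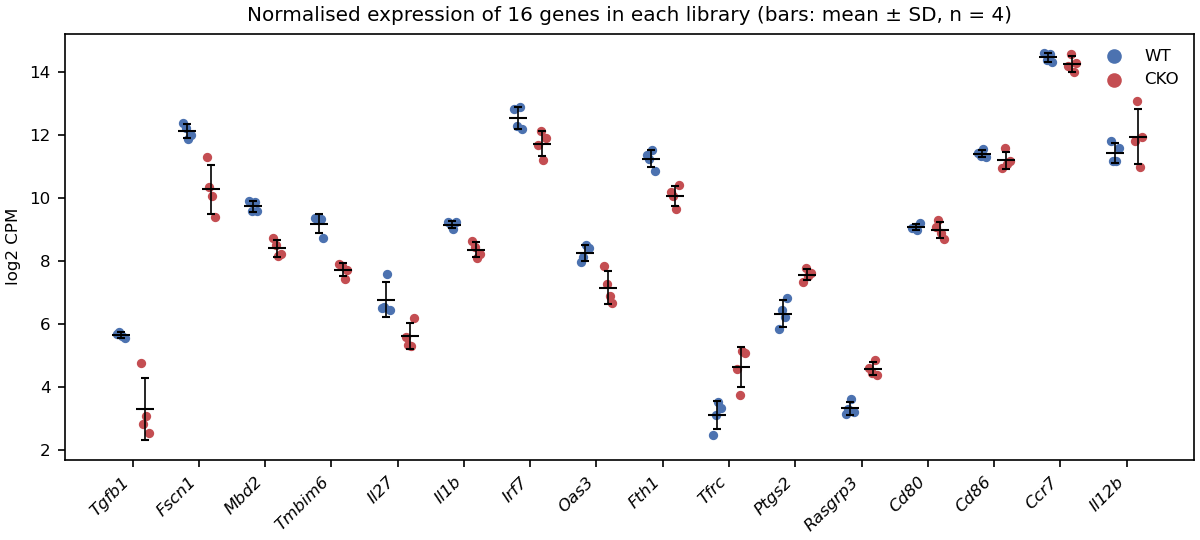
Normalised expression (log2 CPM, vertical axis) of 16 genes in each of 4 WT and 4 CKO libraries. Points are libraries and bars are mean ± SD. Tgfb1 lay between 5.56 and 5.75 in WT and between 2.53 and 4.74 in CKO, while the WT and CKO points of Cd80, Cd86, Ccr7 and Il12b overlapped.

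Dendritic cell activation readouts fixed before the data were examined showed no change past the threshold in any of 10 genes. Ccr7 stood at 22450 ± 2098 CPM in WT and 19590 ± 3388 in CKO. Cd86 stood at 2704 ± 224 and 2361 ± 463 CPM, Cd80 at 541 ± 37.8 and 512 ± 90.0 CPM, and Cd40 at 1808 ± 261 and 1334 ± 280 CPM. Il12b, which encodes the shared subunit of IL-12 and IL-23, stood at 2795 ± 608 and 4514 ± 2855 CPM, with CKO D149 the highest library, and Il6 at 659 ± 67.0 and 515 ± 120 CPM. The log2 fold changes of Cd274, Tnf, Il10 and Tlr9 lay between -0.10 and 0.24. In edgeR's test the smallest adjusted p of the 10 was 0.116, for Cd40; at an unadjusted p, Cd40 and Il6 reached 0.0238 and 0.0486.

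Costimulatory molecules gave 1 lower gene among 17 measured, and the same count adjusted over the list alone: the adhesion gene Icam1 fell from 616 ± 65.4 to 414 ± 66.5 CPM. Of 31 genes of the mature dendritic cell programme, 4 fell, 27 did not pass, and 5 were lower adjusted over the list alone. The 4 were Fscn1, Marcksl1, Traf1 and Pdcd1lg2, which encodes the inhibitory ligand PD-L2 and fell from 324 ± 57.8 to 199 ± 27.1 CPM. The list's median log2 fold change was -0.20, with a camera adjusted p = 0.0175 that became 0.767 (adjusted p) with an estimated correlation. The Benjamini-Hochberg adjustment tied this 0.767 across all 12 lists that camera called and across uncalled lists such as cDC1 markers. It does not tell single lists apart. The median was -0.11 after the GC and length correction (camera adjusted p = 0.0614), -0.09 without CKO D163 (0.119), -0.13 without CKO D169 (0.0491) and -0.08 with the B cell marker covariate (0.697). Among 18 genes of chemotactic receptors and migration only Fscn1 passed the test, at a log2 fold change of -1.69 ± 0.32 (SE); adjusted over the list alone, 1 was higher and 3 lower.

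Of 31 interferon-stimulated genes, 29 had a negative log2 fold change, the median was -0.57, 6 fell and 1 rose. Adjusted over the list alone, 7 were lower and 1 higher. Oasl1 fell from 2471 ± 567 to 1234 ± 274 CPM, Oas3 from 305 ± 52.6 to 149.1 ± 55.9, Oas2 from 51.0 ± 13.7 to 30.6 ± 4.84 and Bst2 from 739 ± 153 to 467 ± 91.1. The other genes past the threshold, named after their values were seen, were Isg15 and Irf7, both lower, and Parp14, which was higher. Camera called the list at an adjusted p = 7.41e-05, against an adjusted p = 0.767 with an estimated correlation. The mean log2 CPM of the list was 9.07 ± 0.29 in WT and 8.57 ± 0.39 in CKO (SD, n = 4), with 3 of 4 CKO libraries below every WT library and CKO D149, at 9.06, among them (exact permutation p = 0.0857, two-sided). Of 19 interferon-gamma-inducible GTPases and partners, 1 rose, Gbp6, in a family of similar genes, and the same count held adjusted over the list alone.

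Inflammatory cytokine genes gave 3 decreases among 19 measured and 5 adjusted over the list alone. Il1b changed by -0.79 ± 0.14 (SE) on the log2 scale, Osm by -0.64 ± 0.12 and Il27, which encodes the regulatory p28 cytokine subunit, by -1.20 ± 0.28. Il15 stood at 257 ± 56.9 CPM in WT and 160 ± 55.9 in CKO and did not pass (edgeR adjusted p = 0.0803). Among 13 chemokines, Cxcl3 fell from 4.16 ± 0.62 to 1.40 ± 0.55 CPM and 3 were lower adjusted over the list alone. Cxcl10 and Ccl5, both interferon-induced, stood at 1727 ± 488 and 1607 ± 542 CPM in WT and at 975 ± 289 and 869 ± 263 CPM in CKO, with edgeR adjusted p-values of 0.0538 and 0.0573. The chemokine list had a median of -0.58 and a camera adjusted p = 0.0175, which was an adjusted p = 0.767 with an estimated correlation. The median was -0.16 over genes with a mean of at least 5 CPM (camera adjusted p = 0.151), -0.35 without CKO D163 (0.116) and -0.41 without WT D142 (0.0776).

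Inhibitory and tolerance-associated genes moved in both directions. Of 31 measured, 5 fell, 2 rose and 24 did not pass; adjusted over the list alone, 8 were lower and 2 higher. Tgfb1, the inhibitory receptor gene Lag3 (log2 fold change -1.28 ± 0.27, SE) and Pdcd1lg2 fell, as did Pirb and Nfil3, named after their values were seen. Ptgs2 rose with a log2 fold change of 1.20 ± 0.19, and Nt5e, also named after its values were seen, rose from 0.88 ± 0.23 to 2.84 ± 1.77 CPM. The list's camera adjusted p = 0.0455 became an adjusted p = 0.767 with an estimated correlation and 0.0561 after the GC and length correction. Its median of -0.27 was -0.15 without WT D154 (camera adjusted p = 0.0826).

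Brakes on NF-κB and Toll-like receptor signalling also moved both ways: of 30 measured, 8 fell and 3 rose, or 12 and 4 adjusted over the list alone. Tnip1, a partner of the ubiquitin editor A20, fell from 227 ± 24.9 to 119 ± 26.3 CPM. Zc3h12a, which encodes the mRNA-degrading enzyme Regnase-1, fell from 41.5 ± 3.19 to 15.1 ± 7.95 CPM, and Cish and the phosphatase gene Dusp5 fell with log2 changes of -0.74 ± 0.15 and -0.95 ± 0.20 (SE). Inpp5d, Dusp4 and Cyld, named after their values were seen, rose. The list's median was -0.13 with a camera adjusted p = 0.0272, and an adjusted p = 0.767 with an estimated correlation; after the GC and length correction the median was 0.02 (camera adjusted p = 0.295). It was -0.24 without CKO D149 or CKO D169 and -0.10 without CKO D163, where the camera adjusted p was 0.0819. With total-count scaling the median was 0.03, against 0.19 for all genes, and the list was still called (camera adjusted p = 0.0167). Of 28 components of TLR9 signalling, 2 fell, the endosomal protease gene Lgmn (1168 ± 110 to 683 ± 119 CPM) and Irf7 (6050 ± 1472 to 3466 ± 911 CPM, with exons that overlap Phrf1), and 3 were lower adjusted over the list alone. Tlr9 itself stood at 2.11 ± 0.59 CPM in WT and 2.02 ± 0.62 CPM in CKO.

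Of 22 genes of MHC class I presentation, 6 fell and 16 did not pass; adjusted over the list alone, 7 were lower and 2 higher. B2m, the light chain of class I molecules, fell from 7648 ± 831 to 4475 ± 844 CPM, the chaperone gene Calr from 450 ± 21.6 to 237 ± 46.3 CPM and the immunoproteasome gene Psmb10 from 473 ± 70.02 to 292 ± 51.3 CPM. H2-T23 fell by 0.63 on the log2 scale, but it belongs to a family of near-identical genes between which reads may be split. Camera gave the class I list an adjusted p = 0.00962, against an adjusted p = 0.767 with an estimated correlation. After the GC and length correction 3 of the 22 were lower, the median moved from -0.22 to -0.11 and the camera adjusted p was 0.0864. Of 16 class II genes, Lgmn alone passed, and the same count held adjusted over the list alone.

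Of 20 genes of the NRF2 and oxidative stress list, 6 fell, none rose, and 7 were lower adjusted over the list alone. Fth1, the heavy chain of the iron store ferritin, fell from 2446 ± 444 to 1085 ± 227 CPM, Sod1 from 37.3 ± 4.51 to 26.0 ± 2.58 CPM and Txnrd1 from 330.0 ± 24.0 to 194 ± 69.6 CPM, and Keap1 changed by -0.49 ± 0.13 (SE) on the log2 scale. The median was -0.32 with a camera adjusted p = 0.00341, and an adjusted p = 0.767 with an estimated correlation; it was -0.17 after the GC and length correction (camera adjusted p = 0.0194) and -0.21 without CKO D163 (0.0335). With the B cell marker covariate the NRF2 list had a camera adjusted p = 0.091. Of 29 lysosomal genes, 3 fell, Atp6v0d1, Lgmn and Npc2, and the same count held adjusted over the list alone. Their median was -0.18 with a camera adjusted p = 0.00962, and an adjusted p = 0.767 with an estimated correlation. The median was -0.11 after the GC and length correction (camera adjusted p = 0.0212) and -0.01 with total-count scaling (0.0196). Of 76 ribosomal protein genes, 5 fell, among them Rpl7a, Rpl39, Rps24 and Rps9, and 0 passed adjusted over the list alone. Camera gave that list an adjusted p = 0.00341, and an adjusted p = 0.767 with an estimated correlation. Its median moved from -0.14 to 0.01 after the GC and length correction, where the list was no longer called (camera adjusted p = 0.549). The median was -0.09 without CKO D149 (camera adjusted p = 0.0258) and 0.03 with total-count scaling (0.0179). It was -0.24 with the B cell marker covariate (camera adjusted p = 1.65e-06).

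**Figure D3:**
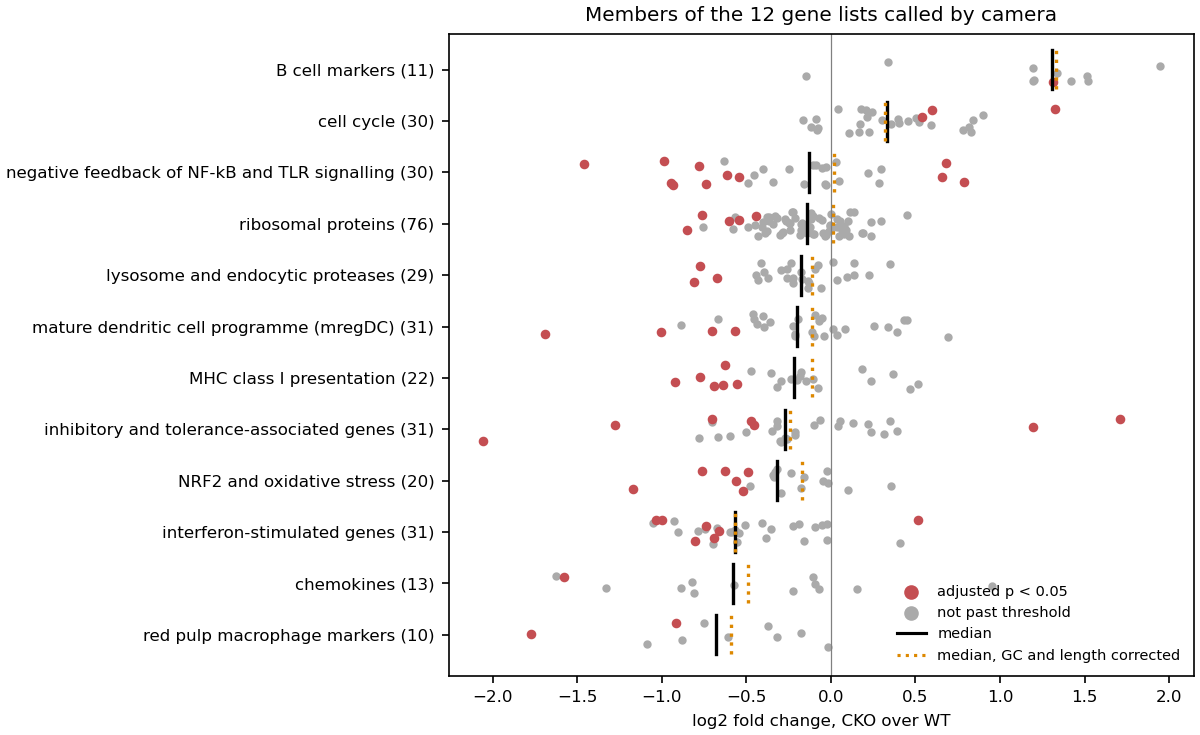
Log2 fold change (CKO over WT, horizontal axis) of the measured members of the 12 lists that camera called, with the number of members in parentheses. Red points passed an adjusted p of 0.05 in edgeR, black lines are medians and dotted lines are medians after GC and length correction. The interferon-stimulated median was -0.57 in both, and the B cell marker median moved from 1.31 to 1.33.

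Camera called 12 of the 38 lists with at least 5 measured members, 10 lower and 2 higher in CKO. With an estimated correlation or by fry's directional test 0 were called, and 5 after the GC and length correction. In fry's mixed test, where members may change in either direction, the 10 lower lists had adjusted p-values from 0.000632 to 0.0401. The cell cycle and B cell lists had 0.197 and 0.211 in it. Lists that camera did not call also passed it, such as TLR9 signalling components (0.00196). Total-count scaling moved the median of all genes from 0.03 to 0.19. It also moved that of the mature dendritic cell list to -0.04, the inhibitory list to -0.12, MHC class I to -0.06, NRF2 to -0.16 and cell cycle to 0.51. Of these lists camera still called all with that scaling except cell cycle (adjusted p = 0.0676). Of the 35 ways to divide the 8 libraries into 4 and 4, 11 called at least 12 lists, so the number of lists called is no more than other divisions of these libraries give. At the level of libraries, 5 lists had all 4 CKO libraries below all 4 WT libraries: inhibitory genes, signalling brakes, MHC class I, lysosome and NRF2. Each then has the smallest exact permutation p that 4 against 4 allows, 0.0286 (two-sided), and over the 38 lists the smallest adjusted p was 0.217. After the GC and length correction only NRF2 kept that value; the exact permutation p was 0.0571 for MHC class I, 0.114 for the inhibitory and lysosome lists and 0.229 for signalling brakes.

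Summed CPM of cDC1 markers was 5911 ± 596 in WT and 5418 ± 897 in CKO (exact permutation p = 0.429), and that of cDC2 markers was 1664 ± 302 and 1387 ± 238 (exact permutation p = 0.171; n = 4 each, two-sided). Of 19 cDC1 markers, 1 rose, the endocytic receptor gene Ly75, from 315 ± 89.6 to 580 ± 103 CPM. Of 20 cDC2 markers, 1 rose, Cd4, from 0.27 ± 0.14 to 1.07 ± 0.43 CPM. Adjusted over each list alone, the counts were the same. Of 41 dendritic cell transcription factors, Tbx21 and Hif1a rose and Nfil3 fell; adjusted over the list alone, 1 was higher and 1 lower.

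B cell markers had a median log2 fold change of 1.31 over 11 genes, of which Ms4a1, which encodes CD20, passed the test (4.43 ± 1.67 to 10.97 ± 4.58 CPM). Camera gave that list an adjusted p = 0.0369, and an adjusted p = 0.767 with an estimated correlation; it was 0.0603 after the GC and length correction, with 0 genes past the threshold. Their summed CPM was 49.1 ± 16.3 in WT and 104 ± 51.9 in CKO (exact permutation p = 0.114, two-sided, n = 4), with CKO D149, at 32.4, as low as the lowest WT library. The immunoglobulin genes Ighm and Igkc, named after their values were seen, rose from 200 ± 47.5 to 454 ± 76.5 CPM and from 85.7 ± 32.1 to 207 ± 66.7 CPM. Red pulp macrophage markers had negative log2 fold changes in all 10 measured genes, with a median of -0.68, or -0.40 without WT D154; Fcgr1 and Spic fell, and 3 were lower adjusted over the list alone. Their summed CPM was 128 ± 21.4 in WT and 74.1 ± 22.7 in CKO (exact permutation p = 0.0286, adjusted p = 0.267 over 14 marker sums), and camera gave an adjusted p = 0.0129, or an adjusted p = 0.767 with an estimated correlation. Cell cycle genes, with a median of 0.33, gave 3 increases among 30 (Kif11, Mcm6 and Rrm1), which held adjusted over the list alone. Their camera adjusted p = 0.0267 was an adjusted p = 0.767 with an estimated correlation and 0.0656 after the GC and length correction. The median was 0.17 without CKO D163 and 0.04 with the B cell marker covariate, and their mean was highest in CKO D163, which also had the highest B cell marker sum.

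**Figure D4:**
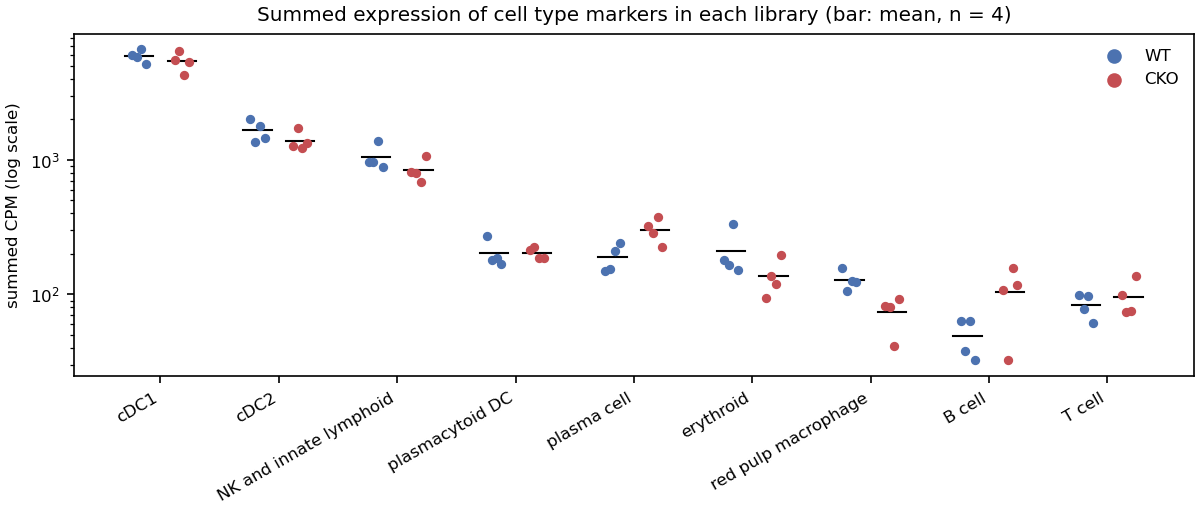
Summed CPM (vertical axis, log scale) of markers of cDC subsets and of other cell types in 4 WT and 4 CKO libraries. Points are libraries and bars are means. B cell markers averaged 49.1 in WT and 104 in CKO, with 1 CKO library at 32.4, and red pulp macrophage markers averaged 128 and 74.1 without overlap.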

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

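The test of a looser sort was chosen only after its result had been seen. Apart from the thinned counts, which were planned, the other tests were chosen after the pattern they weigh was seen, with what each outcome would mean written down before the test was run. Of 172 groups of 4 libraries examined, 10 had a library far from the other 3 by Dixon's criterion, where chance gives about 8.6.

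Among single genes, CKO D149 stood below the other CKO libraries in log2 CPM of Heatr1 (3.53 against 4.64 to 4.77, Dixon ratio 0.898) and of Ablim1 (1.98 against 3.25 to 3.44, ratio 0.871). WT D154 stood above the other WT libraries for Npr1 (3.94 against 3.76 to 3.78, ratio 0.895), and WT D142 below them for Eprs (5.70 against 5.99 to 6.02, ratio 0.924). WT D164 stood above them for Zfp638 (4.38 against 3.84 to 3.92, ratio 0.865) and below them for Tmbim6 (8.72 against 9.31 to 9.34, ratio 0.954). Among list means, WT D142 was low for glycolysis (5.16 against 5.43 to 5.46, ratio 0.875), CKO D163 low for plasmacytoid dendritic cell markers (2.58 against 2.91 to 2.95, ratio 0.876) and WT D154 high for erythroid markers (4.91 against 3.55 to 3.76, ratio 0.848). Ribosomal protein genes took 0.61% of counts in CKO D149 and 0.75% to 0.76% in the other CKO libraries (ratio 0.933).

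The 1038 genes that differed between CKO and WT rise with gene length and fall with GC content, a pattern that low-input amplification can produce. Of 35 divisions of the libraries, 1, the real one, gave as many genes in total, as many higher (503) and as many lower (535). The highest other division gave 0, and 1 of 35 is the smallest share possible. After the correction 972 were called against 1 in the highest other, again 1 of 35. Every other division mixes WT and CKO libraries, so a difference between the genotypes adds to its spread and lowers its calls. The 0 therefore does not measure how many calls chance gives. The share of 1 of 35 argues against a chance division, but not against a cause that goes with genotype. With the B cell marker covariate the count was 407. As the whole cause, GC and length are argued against by the 643 genes that kept their call and sign after the correction, and depth by the 1003 that kept them in thinned counts. For the remaining genes the GC and length trend stays open, as does a biological effect of genotype on long or GC-rich transcripts. The reason is that the library trends go partly with genotype. The exact permutation p was 0.0571 for GC and 0.114 for length (n = 4). The exact permutation adjusted p over 8 library measures was 0.229 for both. For GC, CKO D146 (Spearman 0.12) lay above WT D164 (0.09), and the other CKO libraries lay below every WT library. For length, WT D164 (0.24) lay within the CKO range, and the other WT libraries lay below every CKO library. The difference in the number of lists called is not excluded as chance, since 11 of 35 divisions called at least the 12 lists of the real one and the highest other called 22.

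Interferon-stimulated genes had a median log2 fold change of -0.57. GC and length are argued against as the cause, since the median was -0.57 after the correction and the list remained called by camera. A general fall of genes of like abundance, GC content and length is argued against too: 0 of 10000 matched random lists had as low a median, which is the smallest share they can give (0.01%), and the lowest was -0.36. Random lists do not carry the shared variation of interferon genes between libraries. With the estimated correlation the camera adjusted p was 0.767, the value tied across all 12 called lists. An effect of the genotype on interferon output or response may explain the pattern. Library-to-library variation in interferon exposure also stays open, since CKO D149 lay within the WT range. With the B cell marker covariate the median was -0.44 and the list was not called (camera adjusted p = 0.0699). A link with carry-over of B cells was therefore not decided.

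B cell markers had a median log2 fold change of 1.31, although the sort excluded lineage-positive cells. Support from the list is weak: 1 of 11 markers passed, and 0 did after the GC and length correction. With an estimated correlation the list had the camera adjusted p = 0.767 that was tied across all 12 called lists. The exact permutation p of the sum was 0.114 (adjusted 0.267), with CKO D149 within the WT range. GC and length are argued against by a corrected median of 1.33. For a looser sort that let in all other cells, the marker lists were mixed. Red pulp macrophage markers had a median of -0.68 (-0.40 without WT D154) and NK cell markers -0.12, but T cell markers 0.34 and plasma cell markers 0.80. That test was chosen after its result had been seen, so no conclusion is drawn from it. B cells carried through the sort are a candidate source that was not decided. The markers varied together among libraries of the same genotype (mean pairwise correlation 0.75, against 0.16 at the 95th percentile of random lists). The random lists were matched on CPM only and do not carry the shared variation of B cell genes, so this comparison cannot tell the source. The single gene Ighm kept its call in all 22 alternative fits, with log2 fold changes from 0.88 to 1.37, also with the B cell covariate; whether the genotype changes B cell numbers was not tested.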

How the results depend on the processing

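The GC and length correction and the B cell marker covariate were chosen after seeing the data; all other alternatives were planned. The count of 1038 changed genes (503 higher, 535 lower) was 1989 (960, 1029) with DESeq2, 3461 (1870, 1591) with quality-weighted limma-voom, 407 (256, 151) with the B cell covariate, 8 (1, 7) at an adjusted p of 0.01, 2119 (1102, 1017) at 0.1, and 327 (162, 165) with at least 2-fold as well. With total-count scaling it was 1391 (1080, 311), so 77.6% of calls were higher against 48.5%, and the median of all genes moved from 0.03 to 0.19 on the log2 scale. Without a library the count ran from 70 to 1468, the higher calls from 21 to 921 and the lower calls from 49 to 779; it was lowest without WT D142 (347), WT D150 (82), WT D154 (138), CKO D163 (70) or CKO D169 (457). Under the other alternatives it stayed within 1.5 times. No changed gene took the opposite sign under an alternative, except 6 under the GC and length correction. The cause of these shifts was not tested beyond the fewer libraries or other threshold that some use by construction.

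Lists called numbered 12, but 5 after the GC and length correction, 1 with the B cell covariate, 0 with an estimated correlation and 0 by fry's directional test. Without a library they numbered 6 to 17, with 6 without CKO D163. The interferon-stimulated list kept its call except with the B cell covariate, with an estimated correlation and by fry, with medians from -0.77 to -0.41 over all; its adjusted p was 0.0699 with the B cell covariate. B cell markers changed direction, to -0.06, under their own covariate, by construction.

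Of 124 changed genes followed through every alternative, 21 kept their call in every fit; 21 kept it without CKO D163, 21 without WT D150 and 40 with the B cell covariate. Bcl3 took the opposite sign after the GC and length correction (0.053). Of 1111 values of 49 genes that had not passed, 109 passed under an alternative and 18 changed sign, none of these 18 past the threshold: Cd274, Cd80 and Tlr9 with total-count scaling (0.047, 0.072 and 0.079); Il10, Cd274, Cd80, Tlr9, Bank1 and Mzb1 with the B cell covariate (-0.034, 0.089, 0.075, 0.087, -0.137 and -0.298); Tlr9 with the GC and length correction (0.145); and Tnf with quality weights (-0.118) or the subset covariate (-0.039). Without single libraries, Cd80 ran from -0.188 to 0.009, Tnf from -0.066 to 0.372 and Tlr9 from -0.207 to 0.105. Depth limits little here, and the Y-linked covariate was not run. No paired analysis was possible because the groups share no replicate number.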

Other observations

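The gene lists described first in this part were chosen after the largest changes had been seen, so they are not independent of them. Of 76 ribosome biogenesis genes, 69 had a positive log2 fold change, with a median of 0.55, 17 rose and 0 fell. Nop58, a core protein of box C/D small nucleolar particles, rose from 16.3 ± 3.55 to 38.3 ± 8.61 CPM, Bms1 from 18.3 ± 3.74 to 32.5 ± 4.64 CPM and Mphosph10 from 13.8 ± 1.59 to 29.5 ± 5.06 CPM (n = 4). Camera gave an adjusted p = 6.33e-10, against an adjusted p = 0.268 with an estimated correlation, and the list mean was above all WT libraries in 3 of 4 CKO libraries (exact permutation p = 0.114). The median was 0.65 after the GC and length correction and 0.22 with the B cell marker covariate, under which 2 genes rose; the criteria for these 2 tests were written before they were run, and the second leaves carry-over of B cells undecided. Aminoacyl-tRNA synthetases gave 5 increases (Eprs, Lars, Iars, Rars and Tars) and 1 decrease (Qars) among 20, and all 4 CKO libraries were above all WT libraries (exact permutation p = 0.0286, adjusted p = 0.0714 over 5 lists). Of 23 nuclear import and export receptors, 7 rose, including Xpo4, Ipo7, Cse1l and Xpot, and Kpna4 fell. In fry the adjusted p was 0.0494 for ribosome biogenesis and 0.0441 for the synthetases and for the import and export receptors; in camera with an estimated correlation it was 0.268 for each.

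Among 17 genes of iron uptake and storage, Tfrc rose, while Fth1, the iron-handling gene Pcbp1 and the mitochondrial iron importer gene Slc25a28 fell, of which 1 was lower after the GC and length correction; camera did not call the list (adjusted p = 0.257, and an adjusted p = 0.268 with an estimated correlation), while fry gave an adjusted p = 0.0494.

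Metabolic and stress lists are given as changed genes among those measured. Nuclear-encoded oxidative phosphorylation gave 2 changed genes among 91, mitochondrially encoded mRNAs 0 of 12, cholesterol synthesis 0 of 23, glycolysis 1 of 21 and the proteasome 1 of 37. Cholesterol efflux gave 1 of 11, the unfolded protein response 3 of 23, apoptosis regulators 2 of 25, immediate-early and heat-shock genes 3 of 22, chromatin regulators 2 of 37 and other pattern-recognition receptors 1 of 16. Adjusted over the list alone, immediate-early and heat-shock genes gave 2 higher and 6 lower, and the unfolded protein response 2 higher and 3 lower. By that adjustment apoptosis regulators gave 3 lower, cholesterol efflux 2 lower, glycolysis, the proteasome and other pattern-recognition receptors 1 lower each, and the other lists 0. Adjusted over all genes, immediate-early and heat-shock genes gave 1 higher and 2 lower, but 2 higher and 0 lower after the GC and length correction. Their median moved from -0.16 to -0.01 with it.

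Other cell type markers were mixed. Plasma cell markers were positive in all 7 measured genes with a median of 0.80 and 0 past the threshold, and Irf4, one of them, is also a cDC2 marker. T cell markers had a median of 0.34 and NK cell markers -0.12; Trac rose from 3.13 ± 0.64 to 5.75 ± 0.80 CPM. Erythroid markers had a median of -1.37, with Alas2 lower and Tfrc higher. Plasmacytoid dendritic cell markers had 2 changed genes of 11 and monocyte markers 0 of 11. Of 4 measured Y-linked genes 1 was higher in CKO, or 3 adjusted over the list alone, with a median of 0.67. Neutrophil, platelet, basophil and stromal lists had 1 or 2 measured genes each and were not tested as lists.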
